A study of Arabidopsis thaliana with 12 samples.

How the data were processed

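Expression was measured in 12 array samples, 6 labelled WT and 6 labelled aap6, numbered 1 to 6 in each genotype. The deposited table holds 1 intensity per probe and sample on a linear scale. The array type, dye, background correction and scaling were not given in the sources used here, so the scale and centring of the intensities remain unknown. Of 41268 values, 4318 (10.5%) were exactly 0. Columns were assigned to samples by their own identifiers.

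Gene names came from the platform's annotation, updated through gene identifiers to the TAIR10.1 gene table, which was used for names and gene order only. Of 3439 probes, 692 had 1 gene name, 870 had several and 1877 were not listed. The gene table matched 690 of the 692. No gene was named from a probe with several names.

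Array medians of log2 values differed by more than 0.3, so the deposited intensities were quantile normalized, as specified before the data were examined. Values were then to be raised to a floor at the 10th percentile of all values in the table, and log2 taken. That percentile was 0. After normalization 774 probes held a logarithm of 0 in at least 1 of 10 arrays. All of them fell among the 25% of probes with the lowest mean, which were left out, and 123 of them would have been tested with a floor at the 10th percentile of values above 0 (0.0505). Zeros of WT arrays 1 and 2 stayed finite, so this loss was uneven between the genotypes. It can hide genes that fell to 0 in aap6, and also genes at 0 in the other WT arrays that rose. The floor was kept as specified. The alternatives without normalization, with median centring and without the filter on dim probes used the floor of 0.0505, since zeros have no logarithm there.

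In all, 28 combinations of scaling, floor and handling of replicates were run, most of them before the reported setting was settled, and they gave 77 to 1555 calls. A draft of the whole set of results was also computed with the floor of 0.0505 before the specified floor was restored. The averaging of array pairs departs from the specified fit of 12 arrays. It was chosen from the resemblance of the pairs before any fit was run, and the specified count stands beside the reported one.

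Differences were tested per probe with limma 3.58.1 in R 4.3.3 (lmFit, eBayes), aap6 minus WT, n = 3 against 3 averaged samples, with Benjamini-Hochberg adjustment at 0.05. Named genes were chosen by a rule fixed before the data were examined. It took AAP6 and its family, then the 12 higher and 12 lower genes with the largest absolute log2 change among called probes with 1 gene name and the same sign in every leave-one-out fit, then up to 4 members of each list. The rule was applied to the averaged fit, not to the specified fit of 12 arrays, which may have named other genes. Its sign condition also covered leaving out averaged samples, which was added after seeing the data. A leave-one-out fit in which a probe was not tested was passed over, which concerned 6 of 18 fits for AT1G50510 and none for the other 23 genes named by size. The exact test of the AAP6 transcript over 924 arrangements of arrays and the tests of the fixed lists were not run, since no probe or too few probes carried those names. The 6 groups used in their place were chosen after the data were examined and tested with camera (preset correlation 0.01 and estimated) and fry.

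The numbers were checked for pairing through the correlation, across probes, of deviations from the genotype means. It was 0.275 to 0.345 for arrays of one number and 0.224 to 0.390 for the 3 averaged pairs. All were over 0.1, so the numbers were taken to pair the samples, and the blocked fit is given beside the count. The pairing comes from the data, not from the labels.

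The fit was tested on simulated data for the comparison of aap6 with WT, 3 against 3, over 2579 probes. Of 200 changed probes, 56% of those changed 2-fold and 88% of those changed 4-fold were recovered, with 5 false calls among 149. Noise was drawn independently per probe and sample, without the pairing of numbers, a wide shift between genotypes, zeros or normalization. These rates therefore may not carry over to the measured data. Alternatives were other scalings, floors, filters, variance models, array weights, replicate blocks, a per-probe test with unequal variances, and leaving out each array. Those added after seeing the data were the averaging, the floors taken from values above 0, blocks over the averaged samples, the random effect of the sample, leaving out each averaged sample and comparing scalings and the filter at one floor.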

Results

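Transcript levels were compared between Arabidopsis plants of the ecotype Wassilevskija and an aap6 mutant of the same ecotype. AAP6 encodes an amino acid permease, which the labels place in the xylem parenchyma. The data came from 12 arrays, 6 per genotype, with 3439 probes each. Tissue, growth and array type were not given in the sources used here. The deposited signals were linear and ran from 0 to an upper bound of about 100. Array medians lay between 0.142 and 0.164 in WT and between 0.234 and 0.265 in aap6. Between 334 and 550 probes per WT array and between 236 and 320 per aap6 array were listed at exactly 0. At the upper bound stood 3 to 5 probes per WT array and 2 to 3 per aap6 array, so differences between those probes were not measured. The number of arrays limits the precision.

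Within each genotype, arrays 1 and 2, 3 and 4, and 5 and 6 resembled each other. On the deposited linear scale, correlations across probes were 0.993 to 0.998 within these pairs and 0.955 to 0.980 between other arrays of a genotype. Arrays of different genotypes reached 0.932 to 0.984 on that scale. On log2 values the ranges within a genotype overlapped, at 0.936 to 0.971 and 0.921 to 0.950. On that scale WT arrays 1 and 2 and aap6 array 2 were closest to an array outside their pair, the other arrays to their partner. The labels do not say how the numbered samples relate. Each pair was averaged and counted as 1 sample, which left n = 3 per genotype. Nothing in the labels says that the numbers stand for separate plants, so p-values measure only the spread between these samples, which may be technical.

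**Figure D1:**
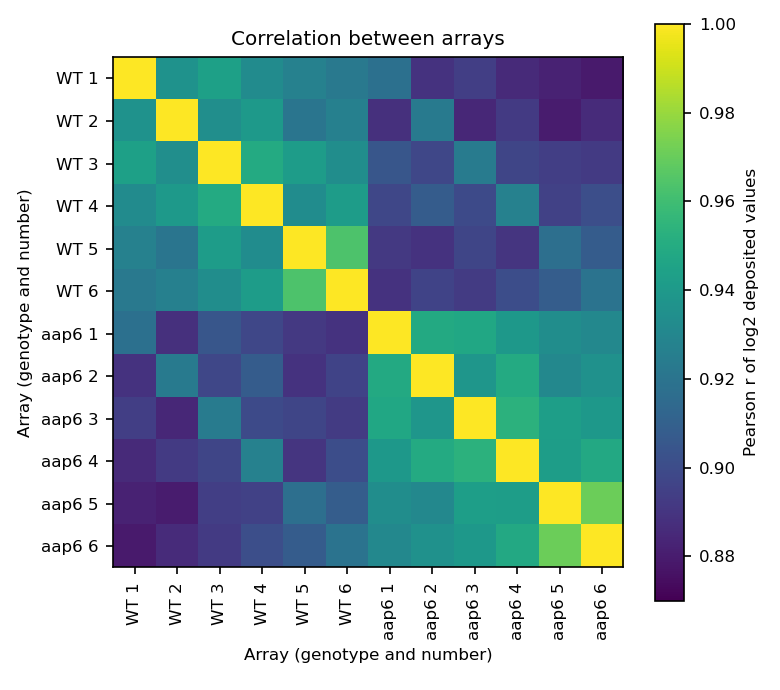
Pearson correlation across probes between the log2 deposited values of each pair of arrays; both axes list the 12 arrays by genotype and number, and colour gives r. Arrays of different genotypes correlated at 0.879 to 0.927, below all pairs of arrays numbered 1-2, 3-4 or 5-6 within a genotype and overlapping the 0.921 to 0.950 of other arrays within a genotype.

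The mutated gene could not be followed. Neither AAP6 nor another member of the amino acid permease family was named on a probe, so the genotype labels had no check from the transcript itself. Of the 251 genes in the 22 lists fixed before the data were examined, 1 had a probe of its own and 3 shared a probe with other genes. No list reached the minimum of 3 measured genes, and no shift of a fixed list was tested. The exception with its own probe was AT3G23940 (DHAD, dihydroxyacid dehydratase of branched-chain amino acid synthesis). Its log2 change, aap6 minus WT, was -0.12 ± 0.20 (SE) and did not pass (limma adjusted p = 0.732). With each array centred on its median the change was -0.77 and passed (limma adjusted p = 0.0335).

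The comparison asked which transcripts differ between the arrays labelled aap6 and those labelled WT. The most strongly changed named genes were higher in aap6. AT4G18180, a pectin lyase-like protein, rose from a mean log2 signal of -4.18 ± 0.47 (SD, n = 3) to -0.41 ± 0.02, a change of 3.77 ± 0.25 (SE). Its WT signal was near the floors tried, so the size depends on the floor, and with the floor at the 25th percentile of all values it was 3.21. AT5G11550, an ARM repeat protein, rose by 3.46 ± 0.24 on the log2 scale, and AT4G35660 rose by 3.08 ± 0.22. The limma adjusted p of all 3 was 0.00136. With the 3 sample pairs as a block it was 0.0149 for AT4G18180, 0.0138 for AT5G11550 and 0.0181 for AT4G35660. Each of these genes was higher in aap6 in 3 of 3 sample pairs. All 130 called probes kept one direction in the 3 pairs, so this adds no separate support.

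Among the other 9 genes of the upper group, AT3G50130 rose by 2.25 and AT3G50180 by 1.51 on the log2 scale. Both belong to the DUF247 family and lie 5 genes apart, and signal shared between such relatives cannot be separated here. The pentatricopeptide repeat gene AT5G39980 rose by 1.99, the TIR-NBS gene AT3G04210 by 1.88 and the Mpv17/PMP22 family gene AT5G19750 by 1.76. Smaller rises were measured for AT1G08845 (1.34), AT-HF (1.32), a histidine biosynthesis enzyme, and AT2G23890 (1.13), and AT5G38310 rose 2.46-fold.

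Rank for rank, the 12 genes with the largest decreases changed less than the 12 with the largest rises. AT3G04500, an RNA recognition motif protein, had a log2 change of -1.72 ± 0.22 (SE), or 3.29-fold lower (limma adjusted p = 0.0108). With the sample pairs as a block its limma adjusted p was 0.0474. The choline transporter-like gene AT1G25500 was 2.83-fold lower. The trigger factor-type chaperone AT5G55220 and AT5G24690 changed by -1.43 and -1.38. PIFI, a chloroplast protein linked to the NDH complex, changed by -1.22. The changes of AT1G50510, AT1G42960, AT3G47980 and AT4G15840 were -1.21, -1.19, -1.15 and -1.11. Those of AT5G46560, AT5G04600 and AT5G48440 were -1.03, -0.98 and -0.87. Without normalization the median log2 change of all probes was 0.50, and the decreases were smaller. AT3G04500 (-0.87) and AT5G46560 (-0.80) stayed called, and the other 8 lower genes tested there did not pass. Their changes lay between -0.48 for AT3G47980 and -0.20 for AT1G42960, with AT1G25500 at -0.42, AT5G24690 at -0.45 and PIFI at -0.30. With each array centred on its median, the median change of all probes was -0.22. The 10 lower genes tested without normalization then ran from -1.60 for AT3G04500 to -0.90 for AT1G42960. The AT1G25500 and AT1G42960 decreases depended on the floor. With the floor at the 25th percentile of all values they were -0.99 and -0.90 and not called (limma adjusted p = 0.0583 and 0.0708). AT5G55220 and AT1G50510 fell below the filter at each floor above 0 tried and were not tested there. An unchanging sign with each array or averaged sample left out, in the fits that tested the probe, was a condition for naming these 24 genes. AT1G50510 was tested in only 12 of those 18 fits and the others in all. Only 6 of them, all higher in aap6, stayed called in every such fit: AT4G18180, AT5G11550, AT4G35660, AT3G50130, AT5G39980 and AT5G19750. Without aap6 array 5 the change of AT1G42960 was -0.72 (limma adjusted p = 0.368).

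**Figure D2:**
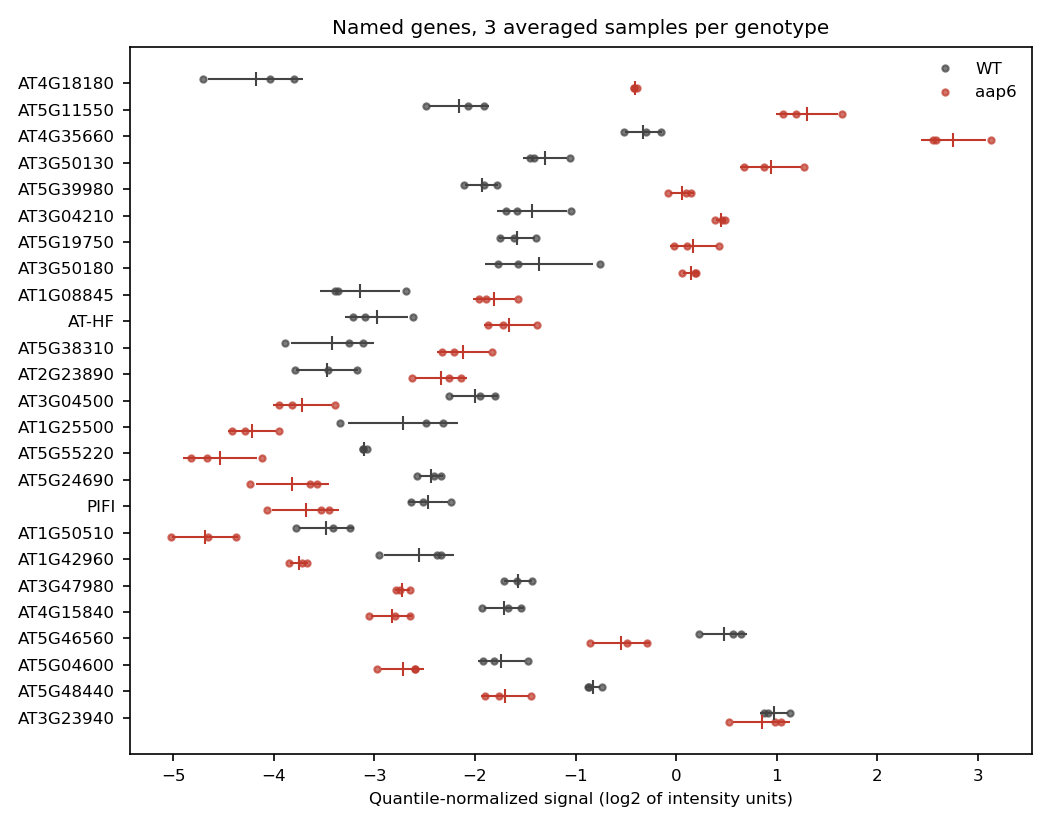
Quantile-normalized log2 signal of the named genes (x axis) in the 3 averaged samples of WT (grey) and aap6 (red); points are samples, vertical marks means and bars the SD. In each of the 24 called genes the 3 aap6 samples lay apart from the 3 WT samples, from AT4G18180 (log2 change 3.77) to AT3G04500 (-1.72), while those of AT3G23940 overlapped. The samples lay apart at all 130 called probes, so this adds no separate support.

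Over all probes, 130 of 2579 tested passed an adjusted p of 0.05 in limma, 86 higher and 44 lower in aap6. Of the 20 probes with the largest absolute changes among them, 19 were higher in aap6, and 4 of the 20 had a single gene name. Among probes called, 29 had 1 gene name, 42 had several and 59 had none. The samples of the genotypes did not overlap at 876 of the 2579 probes, where chance gives 10% for 3 against 3 exchangeable samples. That share leaves out the pairing of the numbers.

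The count rested on the processing. With 12 arrays treated as 12 samples, as the comparison had been specified before the data were examined, 717 probes passed (315 higher, 402 lower). The specified floor, the 10th percentile of all values, was 0 and left no logarithm for some probes. A floor at the 10th percentile of values above 0, chosen after seeing the data, gave 229 (150 higher, 79 lower), including 126 of the 130. Without normalization 880 were higher and 20 lower, and with arrays centred on their medians 198 were higher and 487 lower. The median log2 change of all probes was 0.50, -0.22 and -0.04 as deposited, median centred and quantile normalized. Of the 86 higher and 44 lower calls, 86 and 40 were also tested under the other scalings, which needed the floor above 0. Called in the same direction under all 3 were 77 and 8. With that floor in all 3 scalings, 149 of the 150 higher and 77 of the 79 lower calls were tested throughout, and 131 and 10 of them were called throughout. Samples of the same numbers deviated together across the genotypes, and with the 3 sample pairs as a block 89 probes passed (64 higher, 25 lower), of which 71 were among the 130. With the floor at the 10th percentile of values above 0 the same block raised the count from 229 to 464, so its effect on the count turned with the floor. Of the 24 named genes, 15 passed in the blocked fit. Those that did not were AT3G50180, AT1G08845, AT-HF, AT5G24690, PIFI, AT1G50510, AT5G46560, AT5G04600 and AT5G48440, with limma adjusted p-values up to 0.0661. The count fell to 27 without aap6 arrays 3 and 4, 36 without aap6 arrays 1 and 2, 37 without WT arrays 3 and 4, 61 without WT arrays 5 and 6 and 79 without aap6 arrays 5 and 6.

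**Figure D3:**
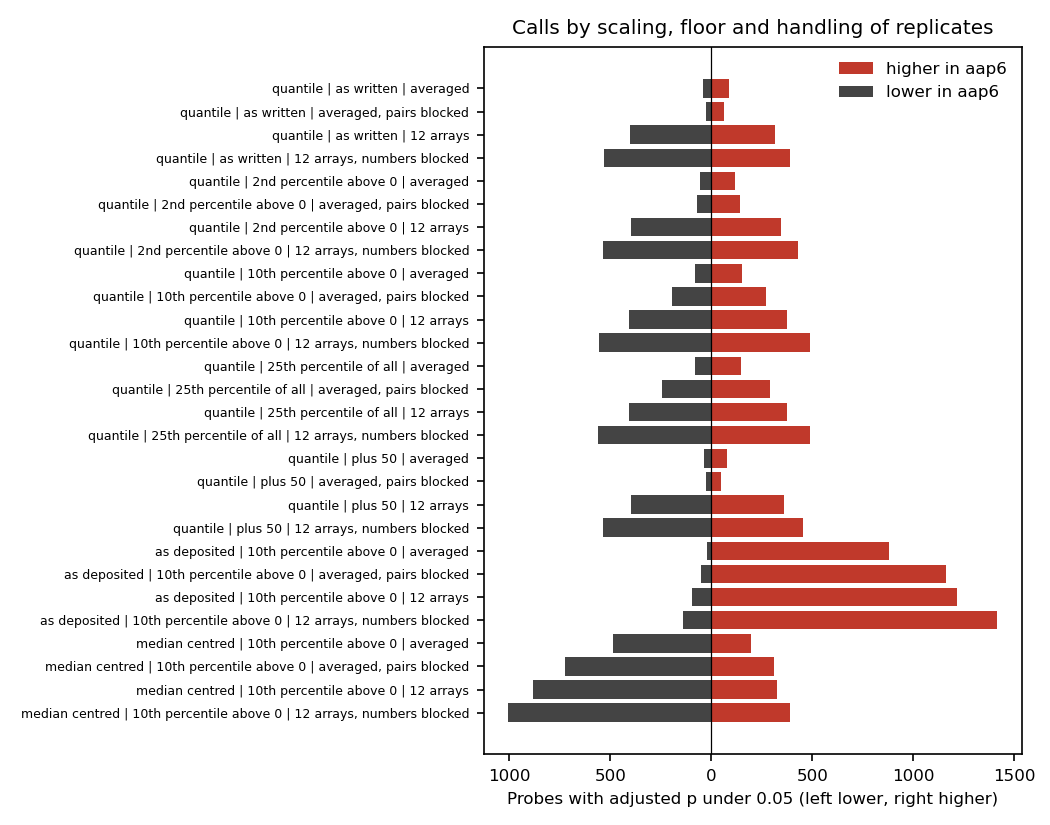
Number of probes with an adjusted p under 0.05 (x axis, higher in aap6 to the right and lower to the left) for 28 combinations of scaling, floor and handling of replicates (y axis). The total ran from 77 to 1555, and the direction of most calls turned with the scaling and, within quantile normalization, with the handling of replicates (86 higher and 44 lower averaged, 315 and 402 as 12 arrays).

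Gene groups were then formed from the names on the probes, after the data had been examined, so their tests are not independent evidence. In none of the 6 groups did camera give an adjusted p under 0.05. Of 11 genes of the photosynthetic light reactions, 1 passed, PIFI, which was lower, and it did not pass with the sample pairs as a block (limma adjusted p = 0.0536). The bright probes of PSBW, LHB1B2, NdhS and PSAN had log2 changes of 0.18 ± 0.17, -0.10 ± 0.20, 0.36 ± 0.17 and -0.39 ± 0.19 (SE). The group's camera adjusted p was 0.742. Fry's test of change in either direction, which compares a group with no other genes, gave an adjusted p of 0.00746. Of the 2579 probes tested, 687 had an unadjusted limma p under 0.05. A small fry value therefore does not set a group apart from other probes.

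None of 8 chloroplast carbon and pigment enzymes passed. PPDK had a log2 change of 0.86 ± 0.27 (adjusted p = 0.107 in limma) and phosphoribulokinase, PRK, one of -0.25 ± 0.23. The camera adjusted p was 0.972, and fry's for either direction 0.0768. None of 6 genes grouped under amino acid, sulfur and nitrogen metabolism passed. AT-HF, which also serves amino acid synthesis and was called, had been left out when the group was formed. Among them ATP sulfurylase APS4 had a log2 change of -0.92 ± 0.26 and ETFQO one of 0.92 ± 0.30, with adjusted p-values of 0.0897 and 0.120 in limma and 0.531 for the group in camera. Fry's adjusted p for either direction was 1.62e-05, the smallest of the 6 groups, and 0.132 for one direction. The smallest unadjusted limma p of a member was 0.0109, for APS4, so no single gene bears out the fry value. Camera gave 0.531 also for 4 cell wall genes and 0.742 for 4 calcium signalling genes, none of which passed, and fry for either direction gave 0.0275 and 0.728. Of 6 transcriptional regulators of development, none passed over all probes and 2 did when adjusted over the list alone. TCP15 had a log2 change of -0.59 ± 0.17 and AGL54 one of -1.16 ± 0.36. That group's camera adjusted p was 0.280, or 0.643 with an estimated correlation, and fry gave adjusted p-values of 0.0262 for one direction and 0.00383 for either.

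A mutant can carry linked sequence around its mutated site, so genes near AAP6 on chromosome 5 were compared with all others. Of 5 tested probes within 200 protein-coding genes on either side, 1 was called, AT5G48440, against 28 of 498 elsewhere (Fisher's exact test, two-sided, p = 0.258). With 5 probes a difference was not measurable with useful precision.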

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

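The alternatives using averaged pairs, floors from values above 0, blocks over sample pairs, the sample as a random effect and leaving out averaged samples were chosen after seeing the data. The count of 130 calls (86 higher, 44 lower) moved by over 1.5 times under most alternatives, and the cause was not tested. It was 900 without normalization (880 and 20) and 685 with median centring (198 and 487). It was 229 with the floor at the 25th percentile of all values (148 and 81) or at the 10th percentile of values above 0 (150 and 79). Without the filter on dim probes, which needed the floor at the 10th percentile above 0, it was 208 (86 lower), to be set against 229 with the filter at that floor. It was 232 over the 1719 brighter probes (139 and 93). With trend and robust eBayes it was 219 (133 and 86), and with array weights 347 (186 and 161). As 12 samples the arrays gave 717 (315 and 402), and 329 with the sample as a random effect (158 and 171). The floor at the 2nd percentile of all values was also 0 and moved nothing, and that of values above 0 gave 172. The offset of 50, far above the array medians, gave 115, of which 73 were among the 130. It took the log2 change of AT4G18180 from 3.77 to 0.020, so sizes under it are not comparable. A per-probe test with unequal variances called 8 higher and 0 lower at the same adjusted threshold, against 86 and 44 in the reported fit. It estimates each variance from only 3 averaged samples, which leaves little power after adjustment. At an unadjusted limma p under 0.05 there were 687 probes.

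With the replicate numbers as a fixed block over 12 arrays, 919 passed (387 and 532), and as a random block 976 (415 and 561). With the 3 sample pairs as a fixed block 89 passed (25 lower), and as a random block 467 (229 and 238). The fixed block of pairs lowered the count at the reported floor and with the offset (115 to 77), and raised it from 172 to 214, 229 to 464 and 229 to 538 with the floors at the 2nd and 10th percentile above 0 and the 25th of all values. As deposited it raised it from 900 to 1211, and median centred from 685 to 1034. The lowest correlation behind the pairing, 0.224, was 0.397 as deposited, 0.400 median centred, 0.437 and 0.403 with the floors at the 25th percentile and the 10th percentile above 0, 0.351 with the 2nd above 0, 0.426 with the offset, 0.403 without the filter and 0.416 over the brighter probes.

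Leaving out single arrays or averaged samples gave 27 to 129 calls, with 23 to 87 higher and 3 to 43 lower. Among single arrays WT 1 moved the count most, to 84. Of 872 alternative values of the 25 named genes, 660 kept sign and call, 210 lost the call and 1 gained it, AT3G23940 with median centring (-0.77). Of the 660, 34 belong to AT3G23940, which was not called in the reported fit. The floor at the 2nd percentile of all values, identical to the reported one, is also counted. So are values with the offset of 50, where sign and call can stay while the change shrinks close to nothing. The other genes were named because they were called from the same arrays, so part of this agreement was fixed in advance. Sign over the leave-outs was also a condition, but all 29 called probes with 1 gene name met it. AT3G23940 ran from -0.22 to 0.043 over the leave-outs, its sign changing without aap6 arrays 1 and 2. The 12 higher genes stayed called as deposited, and 2 of the 10 lower genes tested there did. The median change of all probes was 0.50 as deposited, which favours rises over decreases. The share of genes called near AAP6, 20%, was 0% within 50 genes, with the 3 pairs as a fixed block and with unequal variances. It stayed at 20%, now below the share elsewhere, at an unadjusted p, with median centring, with 12 arrays, with both blocks over 12 arrays and with the random block of pairs. It was 60% as deposited, 100% over the brighter probes, 12.5% within 500 genes and 9.09% without the filter. Few probes lie behind these shares, 5 in the reported setting and 16 within 500 genes, so single probes move them widely. Leave-outs gave 0% to 25%. None of these tests passed. Values near 0 limit the dim probes, whose median SD was 0.487 in the dimmest 25% of those tested and 0.226 in the brightest 25%.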

Other observations

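All tests here except the other splits of the samples and the genes near AAP6 were chosen after the results were seen.

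The 6 averaged samples can be parted into 3 and 3 in 10 ways, too few for a share under 0.05. The real split gave 130 calls, only 1 split (the real one) gave as many, and the highest of the others gave 0. The 4 splits that part all 3 pairs include the real one, and the others of them also gave 0. Every split but the real one mixes the genotypes in both groups. Any difference between genotypes, technical or not, then widens the spread, so the 0 calls do not tell its origin.

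Arrays 1 and 2, 3 and 4, and 5 and 6 of a genotype may be duplicate readings of one sample. In the brightest 25% of probes the variance between pair means was 6.84 times that predicted from within pairs in WT and 7.63 times in aap6. Of 15 ways to pair the arrays, this one had the smallest within-pair variance in both genotypes at the reported floor, but ranked 2 in WT with the floor at the 10th percentile of values above 0. The question stays open.

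WT and aap6 arrays of one number deviated together. The difference between the arrays of a pair correlated across genotypes at 0.161 to 0.378 for the same numbers, and pairs of different numbers reached 0.131. A batch or day shared by both arrays of a pair would cancel in that difference, but whether the pairs are duplicates is open, so a batch or day for each number is not excluded. Spots read for both genotypes on one physical array may also give such a pattern, and this stays open, since different numbers exceeded the limit of 0.1 set for it. If arrays were shared, dye or order could be tied to genotype, which the labels do not settle.

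As deposited, the shift toward aap6 lay mostly in probes of middle signal. With probes ranked by mean signal in 4 bins, 91.8% in bin 2 and 88.2% in bin 3 were higher. In bin 1, the dimmest, and bin 4, the brightest, 63.5% and 60.6% were. The median log2 differences were 0.15, 0.79, 0.60 and 0.10 from bin 1 to bin 4. One scale factor between the genotypes would give equal log2 differences, and the gap of 0.687 between bins 2 and 4 argues against it. One constant offset would give equal linear differences. Their medians were 0.019, 0.076, 0.123 and 0.061 from bin 1 to bin 4. That of bin 3 was 1.61 times that of bin 2, which argues against an offset as the whole cause. A wide rise in the mutant of transcripts in the middle bins stays open and was not tested.

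Linked sequence that differs between the lines could place called genes near one another. Within 20 genes of each other, 1 pair of called genes was found, AT3G50180 and AT3G50130, against a mean of 0.595 in permutations (p = 0.453), so no clustering was shown. Leaving out these DUF247 relatives removed the only pair, so p was 1 by construction, and whether they cross-hybridise was not decided. With calls made at the floor of values above 0 the same permutation test gave p = 0.0336, from 5 pairs, and 0.468 from 2 pairs without these relatives. Of the 3 pairs lost, 2 involved AT3G50270, a gene near both that was called at that floor, not at the reported one, and was singled out after its values were seen, so that value rests on a run of 3 genes called at that floor. It was seen before the reported floor was settled. Around AAP6 itself Fisher's exact test gave p = 0.258 with 5 probes, too few to decide.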
